A study of Homo sapiens with 14 samples.

How the data were processed

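Gene expression was measured in 14 RNA samples of LNCaP cells on Affymetrix arrays, 1 array per sample, with 2 arrays in each of 7 groups. RNA was isolated with a Qiagen RNeasy kit and labelled with biotin following the standard Affymetrix protocol, per the labels. The deposited value table holds linear intensity values for 54613 probe sets, as summarized by the authors, and the second table the same values for 7022 of them. The method of summarization and scaling is not given in the sources used here. The values had no negative entries and close but not identical array medians. Probe sets were joined to genes with the platform annotation: 41091 carried 1 gene symbol (41037 matched by gene identifier, the other 54 kept their symbol), 1801 carried several and 11721 none. Only probe sets with 1 symbol entered the gene analysis, and the one with the highest mean over all arrays stood for its gene, which gave 19775 genes. The 13522 others were tested apart.

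Signals were used as log2(value + 16). All 14 arrays entered 1 linear model of group means in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes with the default prior), with 7 residual degrees of freedom and 2.11 prior degrees of freedom, so that the 2 arrays of a group are assumed to vary like those of the other groups. For each of 8 contrasts p-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used of called genes and lists. No replicate block was used, as nothing states that a replicate number marks a shared day. The contrasts, the tests, 26 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated otherwise. The rule named EZH2, the 6 called genes with the largest rise and the 6 with the largest fall whose arrays did not overlap between groups, up to 4 members per list described with the smallest p, the PRC2 subunits, and 2 other genes that are not reported.

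Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists of a contrast, beside camera with the correlation estimated per list and beside fry, which tests whether the genes of a list move one way without comparing them with other genes. The lists were PRC2 subunits, PRC1 subunits, EZH2-repressed genes of cancer cells, HOX genes, developmental transcription factors bound by PRC2 in embryonic stem cells, S phase and DNA replication, G2 and mitosis, androgen receptor targets, p53 targets, short-lived transcripts, genes raised by HDAC inhibitors in many cell lines, replication-dependent and variant histones, metallothioneins, interferon-stimulated genes, cholesterol synthesis, unfolded protein and ATF4 response, cytosolic heat shock chaperones, neuronal and neuroendocrine genes, cyclins, CDKs and CDK inhibitors, apoptosis regulators, epithelial genes, mesenchymal genes, ribosomal proteins, leukocyte markers, fibroblast and endothelial markers and androgen-independent prostate line markers. Counts of called members are given over all genes and adjusted over the list alone. Of 208 tests camera called 57 at the preset correlation and 0 with an estimated one, and fry called 66. The lists of HDAC inhibitor targets and of EZH2-repressed genes come from the literature, not from these samples. A further 2 lists, NF-kappaB and TNF targets and hypoxia-inducible and glycolysis genes, were set up after the data were examined. The genes raised and lowered by si-EZH2 were tested as sets in the contrast of T350A with wild-type, which shares no arrays with the contrast that chose them but uses the same estimate of spread. Overlaps between lists of called genes were tested with two-sided Fisher's exact tests across genes, and where contrasts share control arrays their correlation was set beside 20 simulations with unchanged groups.

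Simulated data with the spread of the fit tested the steps, but not at the larger add-back and Roscovitine spread. For si-EZH2 against si-Control 16, 40, 47 and 50 of 50 genes changed by log2 0.5, 1, 2 and 4 were recovered and 13 of 19545 unchanged genes called. Of 100 unchanged sets 0 passed after adjustment, which does not test genes that vary together. For TSA against DMSO 14, 41, 50 and 50 genes were recovered. Alternatives were: testing only the genes with the higher mean signal, quantile normalization, shifting each array to the same median, pseudocounts of 1 and 64, the mean of all probe sets of a gene, fitting each experiment alone, a replicate block, an intensity trend with a robust prior, leaving out each array in turn, the 100 genes with the largest moderated statistic as the raised set, and estimated correlations. Leaving out both deviating arrays (Roscovitine replicate 2 and T350A add-back replicate 2), and a term shared by them, were added after the data were examined. Tables used pandas 2.3.3 in Python 3.11.15, figures matplotlib 3.10.9. Array signals give no counts, so no depth is stated beyond the share of probe sets with low signal.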

Results

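Gene expression was profiled in LNCaP cells, an androgen-responsive human prostate cancer line, with Affymetrix arrays that read 54613 probe sets. EZH2 is the catalytic subunit of Polycomb repressive complex PRC2, which methylates histone H3 and represses genes, and the study concerned the phosphorylation of its residue T350. The 14 arrays formed 7 groups of 2. In the drug experiment, untransfected cells received 0.1% DMSO (the solvent), 5 uM TSA (trichostatin A, an inhibitor of histone deacetylases) or 10 uM Roscovitine (an inhibitor of cyclin-dependent kinases, CDKs) for 24 h. In the transfection experiment, cells received for 60 h a control siRNA (si-Control), an siRNA against EZH2 (si-EZH2), or si-EZH2 with a plasmid for siRNA-resistant EZH2, either wild-type (wild-type add-back) or with alanine in place of T350 (T350A add-back). The median signal of an array lay between 107 and 117, and 31.7% to 34.5% of probe sets were under a signal of 50. The number of arrays limits the precision. Nothing states that both arrays of a group came from separate cultures, so the p-values measure only the spread between samples. Replicate 2 of Roscovitine and replicate 2 of the T350A add-back differed from their partners in alike ways: the differences between both replicates of these groups correlated with r = 0.782 across 9887 genes, which are not independent replicates, against -0.337 to 0.399 for the other pairs of groups. Where a signal is under 50, the size and rank of a log2 difference depend on the 16 added to each signal, which understates the ratio. Log2 differences below are given ± SE from the fit over all arrays, with n = 2 arrays per group, and medians of lists are medians of log2 differences.

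The level of EZH2 mRNA shows what the siRNA and the plasmids did. EZH2 (chromosome 7) had a mean signal of 1191 ± 42.8 (SD, n = 2) in si-Control and 393 ± 0.516 in si-EZH2, which was 33.0% of si-Control. Its log2 difference was -1.56 ± 0.07 with an adjusted p of 9.64e-05. The wild-type add-back brought EZH2 to 831 ± 11.7 (69.8% of si-Control) and the T350A add-back to 816 ± 13.8 (68.5%). Both rose over si-EZH2, by 1.05 ± 0.07 (adjusted p = 0.000366) and 1.02 ± 0.07 (adjusted p = 0.000676). EZH2 did not pass the test between the 2 add-back groups (T350A minus wild-type -0.025 ± 0.07, 95% confidence interval -0.19 to 0.14, adjusted p = 0.899). Both stayed lower than si-Control, at -0.51 ± 0.07 for wild-type (adjusted p = 0.00462) and -0.54 ± 0.07 for T350A (adjusted p = 0.00842). In untransfected cells EZH2 was at 1092 ± 9.53 in DMSO, and it fell with TSA to 839 ± 21.3 (-0.37 ± 0.07, adjusted p = 0.00240) and with Roscovitine to 796 ± 75.6 (-0.45 ± 0.07, adjusted p = 0.0179). The add-back calls against si-Control did not hold without si-Control replicate 2, nor that of T350A without si-Control replicate 1, and the Roscovitine call did not hold without either DMSO array or Roscovitine replicate 2.

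**Figure D1:**
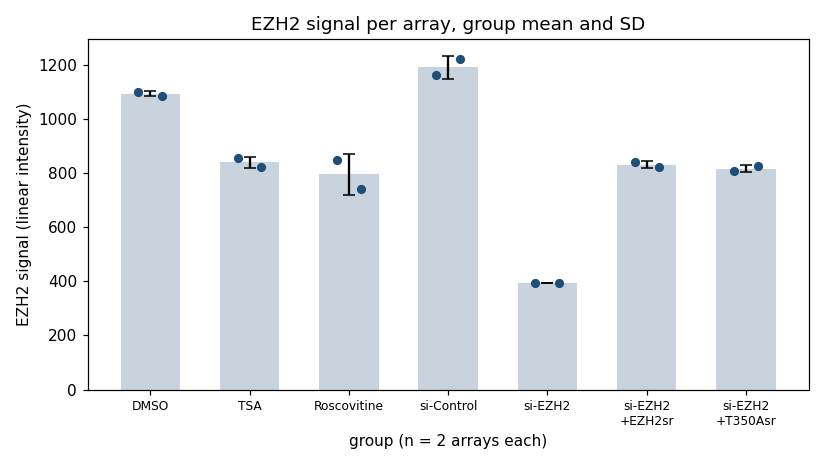
EZH2 signal on a linear axis from 0 in the 7 groups, with bars for group means, error bars for SD and points for the 2 arrays of each group. The mean is 393 in si-EZH2, 831 and 816 in the wild-type and T350A add-back, and 1191 in si-Control.

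**Figure D2:**
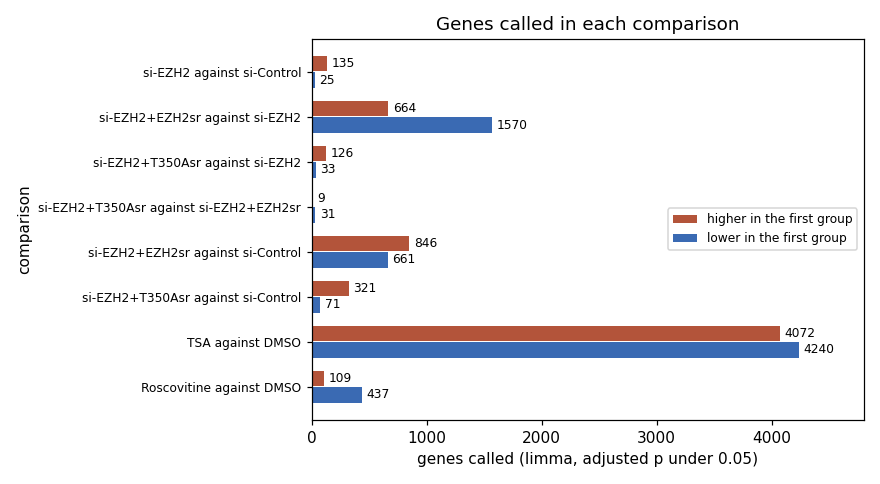
Number of genes called higher and lower by limma (adjusted p under 0.05) in each of the 8 comparisons. TSA has 4072 genes higher and 4240 lower, the wild-type add-back against si-EZH2 664 and 1570, and T350A against wild-type 9 and 31.

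The comparison of si-EZH2 with si-Control asked which genes change when EZH2 is knocked down. EZH2 itself fell most. The largest rises were in TMCO1, a calcium channel (1.46 ± 0.08, signal from 1498 to 4160.2), FYCO1, an autophagy gene (1.44 ± 0.10), PLAAT3, a phospholipase (1.34 ± 0.14), STRADB, a pseudokinase (1.33 ± 0.07), and ZNF658 (1.28 ± 0.10) and FNDC3A (1.19 ± 0.12) (adjusted p from 0.000120 to 0.00558). Untransfected DMSO cells were near the si-EZH2 level for 4 of them (DMSO minus si-EZH2 -0.042 for TMCO1, -0.056 for FYCO1, 0.083 for STRADB and -0.19 for ZNF658) and between both groups for the others (-0.54 for PLAAT3 and -0.53 for FNDC3A). The largest falls after EZH2 were in DIO3, which inactivates thyroid hormone (-1.42 ± 0.20, signal from 1808 to 667), GDF2, a bone morphogenetic protein (-1.07 ± 0.15), PRKACA, a protein kinase A subunit (-0.84 ± 0.11), NOS3, a nitric oxide synthase (-0.80 ± 0.14), and DDC, a decarboxylase (-0.79 ± 0.09), with adjusted p from 0.00701 to 0.0379. EZH2, TMCO1, FYCO1, STRADB and ZNF658 were called in all 14 fits that left out 1 array. PLAAT3 was not called without either si-EZH2 array, FNDC3A without either si-EZH2 array or si-Control replicate 2, DIO3, GDF2, PRKACA and DDC without any si-Control or si-EZH2 array, and NOS3 in 10 of the 14. Further probe sets differed less (0.072 for FYCO1, 0.007 for PLAAT3, 0.075 for FNDC3A and -0.12 for PRKACA) or had the opposite sign (0.20 for NOS3).

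Among the fixed lists, histone genes fell as a group (median -0.30, camera adjusted p = 3.67e-11, adjusted p = 0.117 with estimated correlation). Of 16 measured, 0 rose, 3 fell and 13 did not pass (0 up and 9 down over the list alone). Among those called were H2AC8 (-0.62 ± 0.10), H2BC9 (-0.42 ± 0.07) and H2BC5 (-0.45 ± 0.08). Genes of S phase and DNA replication were higher as a group (median 0.26, camera adjusted p = 6.69e-08, adjusted p = 0.768 with estimated correlation), although 0 rose, 0 fell and 30 did not pass (1 up and 0 down over the list alone). The member with the smallest p, MCM5 (0.63 ± 0.13), a subunit of the replicative helicase, had an adjusted p of 0.0677. Genes of G2 and mitosis were also higher (median 0.18, camera adjusted p = 0.000441, adjusted p = 0.882 with estimated correlation). Of its members, 1 rose, 0 fell and 29 did not pass (4 up and 1 down over the list alone), the single call being TTK, a spindle checkpoint kinase (0.52 ± 0.09). Genes known to rise with HDAC inhibitors were lower (median -0.15, camera adjusted p = 4.70e-05, adjusted p = 0.315 with estimated correlation). Of its members, 0 rose, 1 fell and 27 did not pass (0 up and 6 down over the list alone). The metal-binding metallothioneins were lower too (median -0.17, camera adjusted p = 0.000103, adjusted p = 0.135 with estimated correlation). Of its members, 0 rose, 0 fell and 8 did not pass (0 up and 1 down over the list alone). Genes reported as repressed by EZH2 in cancer cells did not pass as a group (median 0.021, camera adjusted p = 0.899, adjusted p = 0.928 with estimated correlation). Of 21 measured, 0 rose, 0 fell and 21 did not pass (1 up and 1 down over the list alone), and the test pointed down while the median and the mean (0.02) were above 0. Its member IGFBP3, an insulin-like growth factor binding protein, had -0.58 ± 0.11 (adjusted p = 0.0528). Of the 11 PRC2 subunits 0 rose, 1 fell and 10 did not pass (0 up and 1 down over the list alone), the one that fell being EZH2.

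In total, limma called 135 genes higher and 25 lower of 19775 tested, 10 and 3 of them by more than 1 on the log2 scale, and 2255 had an unadjusted p under 0.05. In the DMSO arrays the 135 raised genes lay a median 0.49 above si-Control (quartiles 0.30 and 0.77), against 0.54 in si-EZH2. The number of genes called was 73 without either DMSO array, 103 without either TSA array, 24 without si-Control replicate 1 and 16 without si-Control replicate 2. It was 19 without si-EZH2 replicate 1, 16 without si-EZH2 replicate 2 and 280 without either wild-type add-back array. Under other settings it was 422 with only the genes of higher mean signal, 247 with pseudocount 64 and 83 with the mean of all probe sets of a gene. It was 5 with the arrays of the same experiment alone, 314 with an intensity trend and robust prior and 275 with a term shared by both deviating arrays. The split was 108 higher and 47 lower after quantile normalization, and the 5 list calls stood in every fit that left out 1 array.

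The wild-type add-back against si-EZH2 shows what returning EZH2 changed in knocked-down cells. Chemokines rose: CCL20 (8.37 ± 0.17, signal from 22.4 to 12718), CXCL8 (6.73 ± 0.23, from 50.6 to 7093), CXCL2 (6.06 ± 0.53) and CCL2 (4.91 ± 0.46), which attract leukocytes, the last 2 from 6.17 and 5.51, with SERPINA3, a protease inhibitor (5.70 ± 0.43), and the serpin SERPINB7 (5.08 ± 0.37, from 7.59) (adjusted p from 4.75e-08 to 0.000896). The largest falls were smaller: the cyclin Y-like gene CCNYL2 (-1.85 ± 0.41, signal from 156 to 31.7), the non-coding transcripts LOC100507250 (-1.63 ± 0.34, signal from 42.5 to 2.88) and ARHGEF26-AS1 (-1.60 ± 0.24), KNG1, which encodes kininogen (-1.60 ± 0.30, from 88.2 to 18.5), the neuronal gene LRRN1 (-1.41 ± 0.26), and CDCA7, a gene of dividing cells (-1.30 ± 0.30), with adjusted p from 0.00532 to 0.0266. The rises and ARHGEF26-AS1 were called in all 14 fits that left out 1 array. KNG1, LRRN1 and CDCA7 were not called without either si-EZH2 array, nor CCNYL2 and LOC100507250 without any si-EZH2 or wild-type add-back array. Other probe sets differed less or had the opposite sign (0.06 for CXCL2, -0.18 for CDCA7 and 0.29 for KNG1).

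Cell cycle genes fell. Of 30 genes of G2 and mitosis 0 rose, 28 fell and 2 did not pass (0 up and 29 down over the list alone). The calls included the kinesins KIF23 (-1.15 ± 0.11) and KIF11 (-0.89 ± 0.09) and the mitotic kinase TTK (-0.78 ± 0.09). Together the list had a median of -0.66 (camera adjusted p = 1.46e-18, adjusted p = 0.243 with estimated correlation). Of 30 genes of S phase 0 rose, 17 fell and 13 did not pass (0 up and 28 down over the list alone). They included the DNA primase subunit PRIM1 (-0.64 ± 0.11), the polymerase subunit POLE2 (-0.87 ± 0.15) and cyclin E gene CCNE2 (-0.54 ± 0.10). For the whole list this gave a median of -0.51 (camera adjusted p = 1.08e-11, adjusted p = 0.281 with estimated correlation). Short-lived transcripts rose as a group: 13 rose, 1 fell and 20 did not pass (16 up and 1 down over the list alone). Called members included the phosphatase DUSP1 (1.16 ± 0.11) and the transcription regulators KLF4 (2.10 ± 0.22) and CITED2 (0.98 ± 0.11). The list as a whole had a median of 0.32 (camera adjusted p = 1.87e-09, adjusted p = 0.188 with estimated correlation). Interferon-stimulated genes rose too (median 0.12, camera adjusted p = 0.000433, adjusted p = 0.243 with estimated correlation). Of its members, 8 rose, 1 fell and 24 did not pass (9 up and 2 down over the list alone). Among those called were the RNA sensor IFIH1 (1.46 ± 0.20) and the exonuclease ISG20 (1.46 ± 0.20). Heat shock chaperones (4 up and 0 down of 16, or 6 and 0 over the list alone, such as DNAJA1 (0.63 ± 0.09)), apoptosis regulators (3 up and 1 down of 28, or 5 and 2 over the list alone, with the death receptor FAS (0.65 ± 0.13)) and genes known to rise with HDAC inhibitors (6 up and 1 down of 28, or 7 and 1 over the list alone, with SQSTM1 (0.68 ± 0.07)) also passed (camera adjusted p from 0.000607 to 0.00975, adjusted p from 0.188 to 0.310 with estimated correlation). Of 15 markers of androgen-independent prostate lines 2 rose, CXCL8 (6.73 ± 0.23) and LAMB3 (2.54 ± 0.32), and the list passed (median 0.10, camera adjusted p = 0.0150, adjusted p = 0.243 with estimated correlation), but not without si-EZH2 replicate 2 (median -0.034, adjusted p = 0.124).

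Among p53 targets 5 rose, 1 fell and 18 did not pass (6 up and 1 down over the list alone). The calls included the kinase PLK2 (1.68 ± 0.20) and the growth factor GDF15 (0.47 ± 0.07). Together the list had a median of 0.049 (camera adjusted p = 0.0220, adjusted p = 0.310 with estimated correlation), and the call was lost without si-EZH2 replicate 1 or wild-type add-back replicate 2 (median 0.0073 to 0.052, adjusted p from 0.0561 to 0.127). Among histones 2 rose, 1 fell and 13 did not pass (3 up and 1 down over the list alone). They included H2BC5 (0.32 ± 0.08) up and H2AX (-0.66 ± 0.15) down. For the whole list this gave a median of 0.092 (camera adjusted p = 0.0220, adjusted p = 0.368 with estimated correlation), and the call was lost without si-EZH2 replicate 2 or wild-type add-back replicate 1 (median 0.05 to 0.10, adjusted p from 0.0564 to 0.145). Androgen receptor targets were lower as a group (median -0.21, camera adjusted p = 0.0475, adjusted p = 0.432 with estimated correlation). Of its members, 1 rose, 4 fell and 15 did not pass (1 up and 8 down over the list alone). Called members included the kallikrein KLK2 (-1.02 ± 0.21) and the phosphatase ACP3 (-0.53 ± 0.14) down but NDRG1, also induced by low oxygen, up (1.86 ± 0.17). That call was lost without any DMSO, TSA, Roscovitine or si-Control array, without si-EZH2 replicate 1 and without wild-type add-back replicate 1 (median -0.11 to -0.21, adjusted p from 0.0521 to 0.277). EZH2-repressed genes from the literature did not pass (median 0.055, camera adjusted p = 0.0877, adjusted p = 0.243 with estimated correlation). Of its members, 3 rose, 1 fell and 17 did not pass (4 up and 3 down over the list alone). Among those called were IGFBP3 (1.57 ± 0.11), CDKN2A (0.41 ± 0.10) and CDKN1C (0.45 ± 0.12) up and MSMB (-0.53 ± 0.11) down. The sign of CDKN2A, a CDK inhibitor gene, turned to -0.04 with the mean of all its probe sets. In total, limma called 664 genes higher and 1570 lower of 19775 tested, 181 and 37 of them by more than 1 on the log2 scale, and 4923 had an unadjusted p under 0.05. The count was 611 without si-EZH2 replicate 1, 458 without si-EZH2 replicate 2 and 826 without wild-type add-back replicate 1, and 244 with the arrays of the same experiment alone. With each array at the same median the split was 799 higher and 1183 lower.

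The T350A add-back against si-EZH2 asked the same of EZH2 that cannot be phosphorylated at T350. Its largest rises were again CCL20 (8.31 ± 0.17, signal from 22.4 to 12195), CXCL2 (7.04 ± 0.53), CXCL8 (6.79 ± 0.23), SERPINA3 (5.06 ± 0.43) and CCL2 (4.97 ± 0.46) (CXCL2 and CCL2 from 6.17 and 5.51), and the chemokine CCL8 (4.73 ± 0.33) (adjusted p from 5.05e-08 to 0.00219). The largest falls were PDZD4 (-1.04 ± 0.18, signal from 21.3 to 2.16), at low signal in both groups, RIPOR2, an inhibitor of the GTPase RhoA (-0.94 ± 0.09), the adhesion molecule gene AMIGO2 (-0.93 ± 0.15), the tight junction gene CLDN8 (-0.87 ± 0.16), NANOS1 (-0.78 ± 0.13) and LYPD3 (-0.72 ± 0.11) (adjusted p from 0.00299 to 0.0475). The rises and RIPOR2 were called in all 14 fits that left out 1 array. The others were lost, PDZD4 and CLDN8 without any si-Control, DMSO, Roscovitine or si-EZH2 array, among others, AMIGO2 without any drug or si-EZH2 array or T350A add-back replicate 1, NANOS1 without any TSA, si-Control or si-EZH2 array or T350A add-back replicate 1, and LYPD3 without any si-EZH2 or T350A add-back array. Other probe sets differed less (0.52 for CXCL2) or had the opposite sign (0.077 for NANOS1).

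Genes of G2 and mitosis fell as a group (median -0.34, camera adjusted p = 4.76e-14, adjusted p = 0.486 with estimated correlation). Of 30 measured, 0 rose, 4 fell and 26 did not pass (0 up and 12 down over the list alone). The calls included TTK (-0.62 ± 0.09), KIF23 (-0.71 ± 0.11), BUB1 (-0.45 ± 0.08) and DLGAP5 (-0.47 ± 0.08). S-phase genes were lower (median -0.15, camera adjusted p = 6.98e-05, adjusted p = 0.550 with estimated correlation). Of its members, 0 rose, 1 fell and 29 did not pass (0 up and 1 down over the list alone), the one called being CCNE2 (-0.63 ± 0.10). Short-lived transcripts rose (median 0.30, camera adjusted p = 3.84e-08, adjusted p = 0.310 with estimated correlation). Of its members, 8 rose, 0 fell and 26 did not pass (15 up and 2 down over the list alone). They included the transcription factors JUNB (2.14 ± 0.23), KLF4 (1.96 ± 0.22) and EGR1 (0.83 ± 0.10). Of the androgen-independent line markers 1 rose, CXCL8 (6.79 ± 0.23) (median 0.21, camera adjusted p = 0.00139, adjusted p = 0.310 with estimated correlation). Heat shock chaperones were higher as a group (median 0.13, camera adjusted p = 0.00352, adjusted p = 0.310 with estimated correlation). Of its members, 0 rose, 0 fell and 16 did not pass (2 up and 0 down over the list alone). The unfolded protein and ATF4 response list (median 0.057, camera adjusted p = 0.0495, adjusted p = 0.486 with estimated correlation), with 1 of 26 up, the stress factor ATF3 (1.26 ± 0.23), was just past the threshold. So were interferon-stimulated genes (median 0.10, camera adjusted p = 0.0495, adjusted p = 0.486 with estimated correlation), 0 up and 0 down of 33, or 0 and 0 over the list alone. Both calls were lost without any TSA or Roscovitine array, without si-EZH2 replicate 1 and without T350A add-back replicate 2, and 1 or the other without DMSO, si-Control, wild-type add-back or T350A add-back replicate 1 arrays (median -0.013 to 0.057, adjusted p from 0.0512 to 0.136 and median 0.051 to 0.15, adjusted p from 0.0583 to 0.319). Both were lost too without both deviating arrays (median -0.013, adjusted p = 0.164 and median 0.065, adjusted p = 0.176). The median of the first list was below 0 without T350A add-back replicate 2, and 0.0064 with a term shared by these arrays. EZH2-repressed genes did not pass (median 0.0066, camera adjusted p = 0.383, adjusted p = 0.550 with estimated correlation). Of its members, 0 rose, 0 fell and 21 did not pass (2 up and 0 down over the list alone).

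In total, limma called 126 genes higher and 33 lower of 19775 tested, 76 and 1 of them by more than 1 on the log2 scale, and 2514 had an unadjusted p under 0.05. Of the 126 higher genes 115 were also higher in the wild-type add-back (4.23 for independent lists), and of the 33 lower genes 32 were also lower (2.62). Both comparisons share the si-EZH2 arrays: across genes, which are not independent replicates, their log2 differences correlated with r = 0.684 against 0.5003 in simulated unchanged groups, with a covariance of 0.0730 against 0.0174. The count was 97 without either DMSO array, 105 without either TSA array, 100 without either si-Control array and 39 without si-EZH2 replicate 1. It was 31 without si-EZH2 replicate 2, 338 without either wild-type add-back array, 93 without T350A add-back replicate 1 and 314 without T350A add-back replicate 2. It was 402 with only the genes of higher mean signal, 265 with pseudocount 64 and 4 with the arrays of the same experiment alone. It was 369 with an intensity trend and robust prior and 320 without both deviating arrays, and the split was 128 higher and 73 lower after quantile normalization and 113 higher and 56 lower with each array at the same median.

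**Figure D3:**
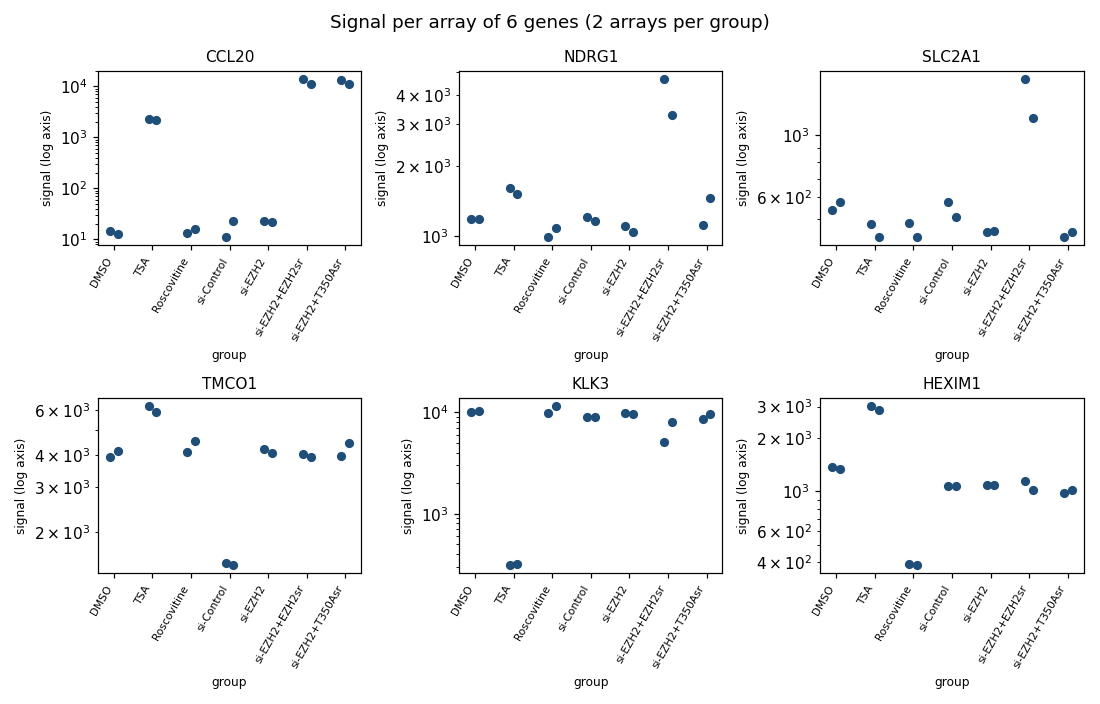
Signal (log axis) of CCL20, NDRG1, SLC2A1, TMCO1, KLK3 and HEXIM1 on each of the 14 arrays, 1 point per array, by group. CCL20 is at 11267 and 14169.7 in the wild-type add-back arrays and at 21.8 and 23.0 in si-EZH2, and SLC2A1 at 1156 and 1599 in the wild-type and 431 and 449.6 in the T350A add-back.

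The direct comparison of both add-backs asked what loss of the phosphorylation site changes. The largest differences were genes lower in T350A: HMOX1, haem oxygenase (-1.68 ± 0.23, signal from 4805 to 1506), PFKFB3, a regulator of glycolysis (-1.67 ± 0.16), NDRG1 (-1.61 ± 0.17), the glucose transporter SLC2A1 (-1.59 ± 0.14), the glycolytic enzyme ENO2 (-1.59 ± 0.19) and ANKRD37, a hypoxia-inducible gene (-1.53 ± 0.14), with adjusted p from 0.0156 to 0.0301. Genes higher in T350A were the glutamate transporter SLC1A3 (1.06 ± 0.13, signal from 8.43 to 34.9), the ubiquitin ligase TRIM2 (0.75 ± 0.09), the scavenger receptor MARCO (0.71 ± 0.11, signal from 2.23 to 13.8), the non-coding LRP8-DT (0.62 ± 0.08), the transcription factor SOX13 (0.61 ± 0.08) and AHNAK2 (0.57 ± 0.08), with SLC1A3 and MARCO at low signal in both groups (adjusted p from 0.0205 to 0.0485). The genes lower in T350A had been raised in the wild-type add-back: NDRG1, for example, had a signal of 1075 in si-EZH2, 3998 with wild-type and 1289.5 with T350A. On a list of 50 hypoxia-inducible and glycolysis genes, set up after these values were seen, 36 rose in wild-type against si-EZH2 (median 0.69) and 4 in T350A (median 0.078), and 14 were lower in T350A than in wild-type (median -0.49). None of the 12 genes named here was called in every fit that left out 1 array: all were lost without either TSA array, ANKRD37 also without wild-type add-back replicate 1, and the others except PFKFB3, NDRG1 and SLC2A1 also without any si-Control or si-EZH2 array and wild-type add-back replicate 1, among others. Other probe sets differed less (-0.33 for SLC2A1) or had the opposite sign (-0.34 for TRIM2, -0.18 for AHNAK2 and 0.31 for ANKRD37).

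Genes of G2 and mitosis (median 0.37, camera adjusted p = 1.02e-09, adjusted p = 0.553 with estimated correlation) and of S phase (median 0.32, camera adjusted p = 7.46e-08, adjusted p = 0.553 with estimated correlation) were higher in T350A as groups. Adjusted over the list alone, 20 of 30 and 16 of 30 were up. Over all genes limma called 0 of them, as with KIF11 (0.41 ± 0.09), HMMR (0.41 ± 0.10), UHRF1 (0.77 ± 0.20) and MCM7 (0.30 ± 0.09) (adjusted p from 0.127 to 0.179). Interferon-stimulated genes were lower (median -0.10, camera adjusted p = 0.00509, adjusted p = 0.553 with estimated correlation), with 2 of 33 down over the list alone, and that call was lost without wild-type add-back replicate 1 or T350A add-back replicate 1 (median -0.079 to -0.085, adjusted p from 0.0547 to 0.0572). EZH2-repressed genes did not pass (median 0.014, camera adjusted p = 0.223, adjusted p = 0.553 with estimated correlation): 1 of 21 was lower, IGFBP3 (-1.03 ± 0.11), and the test and the mean (-0.044) pointed down while the median was above 0. In total, limma called 9 genes higher and 31 lower of 19775 tested, 1 and 14 of them by more than 1 on the log2 scale, and 3233 had an unadjusted p under 0.05. Without either TSA array limma called 0 genes (2938 at an unadjusted p under 0.05), and the arrays of the same experiment alone also gave 0 (2425). The count was 19 without either DMSO array and 19 without either Roscovitine array. It was 6 without either si-Control array, 7 without either si-EZH2 array and 13 without wild-type add-back replicate 1. It was 1008 without wild-type add-back replicate 2, 26 without T350A add-back replicate 1 and 135 without T350A add-back replicate 2. It was 164 with only brighter genes, 77 after quantile normalization, 78 at equal medians and 74 with pseudocount 64. It was 14 with the mean of all probe sets of a gene and 112 with an intensity trend and robust prior.

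If T350A were less able to repress, genes raised by the knockdown would stay higher with it than with wild-type EZH2. The 135 genes raised by si-EZH2 were chosen without the add-back groups but with the shared spread. Their median T350A minus wild-type log2 difference was 0.10 (quartiles 0.0043 and 0.21), 102 above 0, against 0.063 over all genes. Camera gave the set p = 0.000301, and p = 0.101 with estimated correlation. Of single genes, 1 was called higher and 1 lower in T350A. Against si-EZH2, 62 of the 135 were called lower with wild-type EZH2 and 6 with T350A, while 68 and 71 were still called higher than si-Control. As these si-EZH2 arrays also chose the set, the fall was measured again with each si-EZH2 array held out in turn: over 17 and 14 genes the median was -0.083 and -0.21 for wild-type and -0.086 and -0.19 for T350A. The 24 genes lowered by si-EZH2 besides EZH2 had a median difference of 0.024, with the test pointing down (camera p = 0.721, p = 0.860 with estimated correlation), and this median turned negative under quantile normalization (-0.031), equal medians (-0.072), the mean of probe sets (-0.063) and a trended prior (-0.00370). With camera at the preset correlation, the shift of the raised genes lost its call without si-EZH2 replicate 1 (0.028, p = 0.412) or 2 (0.05, p = 0.0729), was 0.05 without si-Control replicate 2 and 0.17 without wild-type add-back replicate 2. At this correlation it was also lost after quantile normalization (0.026, p = 0.130), with equal medians (0.00790, p = 0.261) and with the transfection arrays alone (0.047 over 4 genes, p = 0.634).

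**Figure D4:**
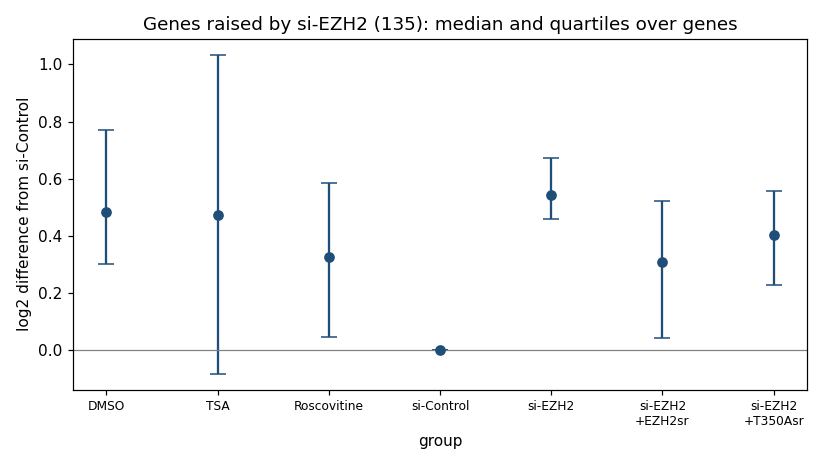
Median and quartiles over the 135 genes raised by si-EZH2 of the log2 difference from si-Control in each group. The median is 0.54 in si-EZH2, 0.31 and 0.40 in the wild-type and T350A add-back, and 0.49 in DMSO.

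Against si-Control, chemokines in both add-back groups were far above control: CCL20 (8.62 ± 0.17 with wild-type, 8.57 ± 0.17 with T350A), CXCL8 (7.25 ± 0.23, 7.32 ± 0.23), CXCL2 (6.12 ± 0.53, 7.10 ± 0.53) and CCL2 (5.19 ± 0.46, 5.25 ± 0.46), from si-Control signals of 1.68 to 30.3. SERPINA3 (5.30 ± 0.43) and the cytokine IL32 (4.78 ± 0.37, signal from 1 to 518) were among the 6 largest rises with wild-type, and TNFAIP3, an inhibitor of NF-kappaB signalling (4.77 ± 0.34), and CCL8 (4.76 ± 0.33) among those with T350A. The largest falls with wild-type were LOC100507250 (-1.74 ± 0.34, signal from 48.7 to 2.88), CCNYL2 (-1.72 ± 0.41), KNG1 (-1.64 ± 0.30) and ARHGEF26-AS1 (-1.48 ± 0.24) (CCNYL2 and KNG1 to 31.7 and 18.5) and the relaxin hormones RLN2 (-1.39 ± 0.17) and RLN1 (-1.38 ± 0.14). With T350A they were KNG1 (-1.54 ± 0.30, signal from 92.3 to 20.7), DDC (-1.05 ± 0.09), CATSPERH (-1.04 ± 0.20, signal from 24.1 to 3.31), the CDK inhibitor CDKN2D (-0.98 ± 0.15), KLHL1 (-0.96 ± 0.14) and the vesicle GTPase RAB3A (-0.96 ± 0.16). All of these had adjusted p from 3.61e-08 to 0.0378. The rises, RLN1, RLN2 and DDC were called in all 14 fits that left out 1 array, and the other falls were lost without a si-Control array, among others. Other probe sets differed less or had the opposite sign with wild-type (-0.23 for CXCL2 and 0.29 for KNG1) and with T350A (0.36 for CXCL2, 0 for KNG1, 0.024 for DDC, -0.24 for CDKN2D and -0.023 for KLHL1).

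With wild-type, genes of G2 and mitosis were lower than in si-Control (median -0.47, camera adjusted p = 2.20e-15, adjusted p = 0.246 with estimated correlation). Of its members, 0 rose, 13 fell and 17 did not pass (0 up and 27 down over the list alone), such as KIF23 (-0.91 ± 0.11), BIRC5 (-1.07 ± 0.14) and NUSAP1 (-0.57 ± 0.08). With T350A 0 rose, 0 fell and 30 did not pass (0 up and 2 down over the list alone) (median -0.12, camera adjusted p = 5.51e-06, adjusted p = 0.680 with estimated correlation), a call lost without T350A add-back replicate 1 (median -0.045, adjusted p = 0.0619). Short-lived transcripts were higher in both, with 13 of 34 up with wild-type (median 0.28, camera adjusted p = 1.25e-09, adjusted p = 0.215 with estimated correlation) and 8 with T350A (median 0.36, camera adjusted p = 2.68e-07, adjusted p = 0.145 with estimated correlation), among them JUNB (2.02 ± 0.23, 2.54 ± 0.23) and KLF4 (2.36 ± 0.22, 2.22 ± 0.22). Metallothioneins were lower in both (median -0.27, camera adjusted p = 0.00276, adjusted p = 0.215 with estimated correlation, and median -0.27, camera adjusted p = 4.87e-06, adjusted p = 0.130 with estimated correlation), with 3 and 1 of 8 called, among them MT1X (-0.50 ± 0.09) with wild-type and MT2A (-0.35 ± 0.07) with T350A. Histones were lower in both (median -0.16, camera adjusted p = 0.00612, adjusted p = 0.296 with estimated correlation, and median -0.23, camera adjusted p = 2.68e-07, adjusted p = 0.145 with estimated correlation), with 1 and 3 of 16 called, H2AC6 in both (-0.44 ± 0.07, -0.44 ± 0.07). The wild-type histone call was lost without wild-type add-back replicate 2 (median -0.084, adjusted p = 0.220). Androgen-independent line markers passed in both (median 0.12, camera adjusted p = 0.0481, adjusted p = 0.296 with estimated correlation for wild-type, and median 0.21, camera adjusted p = 0.0207, adjusted p = 0.404 with estimated correlation for T350A), with 3 and 1 of 15 up, CXCL8 in both. With wild-type that call was lost in 10 of the 14 fits that left out 1 array (median 0.053 to 0.12, adjusted p from 0.0506 to 0.0912), with T350A without T350A add-back replicate 1 (median 0.28, adjusted p = 0.157).

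In the wild-type add-back, interferon-stimulated genes (7 up of 33, with IFIH1 (1.69 ± 0.20) and IFI44 (1.05 ± 0.15)), p53 targets (4 up of 24, with PLK2 (1.93 ± 0.20) and FAS (0.70 ± 0.13)), heat shock chaperones (5 up of 16) and apoptosis regulators (4 up and 1 down of 28) were also higher than in si-Control. S-phase genes were lower (1 down of 30, RRM2 (-0.50 ± 0.12)). These 5 lists had camera adjusted p from 0.000174 to 0.0113, adjusted p from 0.215 to 0.609 with estimated correlation. In T350A the camera adjusted p of these lists was 0.0547 to 0.594. Of these lists, interferon-stimulated genes and S-phase genes passed in the direct comparison of both add-back groups, and the other 3 did not. The p53 call was lost without wild-type add-back replicate 2 (median 0.082, adjusted p = 0.0538) and the S-phase call without replicate 1 (median -0.057, adjusted p = 0.293). For wild-type against si-Control, limma called 846 genes higher and 661 lower of 19775 tested, 208 and 38 of them by more than 1 on the log2 scale, and 4271 had an unadjusted p under 0.05. For T350A, limma called 321 genes higher and 71 lower of 19775 tested, 98 and 3 of them by more than 1 on the log2 scale, and 2882 had an unadjusted p under 0.05. The wild-type count was 992 without either DMSO array, 462 without si-Control replicate 1 and 381 without si-Control replicate 2. It was 639 without wild-type add-back replicate 1 and 2328 without wild-type add-back replicate 2. For T350A the count was 232 without either DMSO array, 85 without si-Control replicate 1 and 74 without si-Control replicate 2. It was 619 without either wild-type add-back array and 259 without T350A add-back replicate 1. Under other settings the wild-type count was 238 with the arrays of the same experiment alone, and the T350A count 787 with only the genes of higher mean signal, 20 with the arrays of the same experiment alone and 714 with an intensity trend and robust prior. After quantile normalization the splits were 901 higher and 1068 lower for wild-type and 259 higher and 175 lower for T350A, the latter 229 higher and 124 lower at equal medians.

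TSA against DMSO asked which genes respond to inhibition of histone deacetylases. The largest rises were the cytochrome CYP4F2 (7.64 ± 0.23), with signal from 15.0 to 6011, the microRNA host gene MIR7-3HG (6.92 ± 0.13), the non-coding LINC01419 (6.44 ± 0.16), the imprinted gene PEG10 (5.56 ± 0.17) and the chemokines CCL20 (6.25 ± 0.17) and CXCL2 (5.53 ± 0.53), all from DMSO signals of 1.91 to 38.4. The largest falls included the androgen-driven kallikreins KLK2 (-5.96 ± 0.21, signal from 4064 to 49.8) and KLK3, which encodes prostate-specific antigen (-4.95 ± 0.18, from 10266 to 317), the growth regulator MYC (-5.45 ± 0.26), NETO1 (-4.79 ± 0.07), the chemokine scavenger ACKR3 (-4.78 ± 0.19) and the ETS factor ETV1 (-4.54 ± 0.10). These had adjusted p from 1.04e-09 to 2.10e-05, and all were called in all 14 fits that left out 1 array. Other probe sets differed less (0.13 for CXCL2 and -0.21 for KLK3) or had the opposite sign (0.50 for KLK2 and 0.083 for ACKR3).

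Of 28 genes known to rise with HDAC inhibitors 23 rose, 0 fell and 5 did not pass (24 up and 0 down over the list alone). Called members included the chaperone CLU (4.06 ± 0.09), the oxidoreductase DHRS2 (5.17 ± 0.16) and SERPINI1 (3.44 ± 0.13). Together the list had a median of 1.32 (camera adjusted p = 4.28e-12, adjusted p = 0.0531 with estimated correlation). Metallothioneins rose (7 up and 0 down of 8, or 7 and 0 over the list alone, with MT1G (3.10 ± 0.07), MT1F (2.78 ± 0.07) and MT1H (2.90 ± 0.09); median 2.11, camera adjusted p = 6.17e-07, adjusted p = 0.0531 with estimated correlation), and so did histone genes (12 up and 2 down of 16, or 12 and 2 over the list alone, with H2AC8 (3.04 ± 0.10) and H1-2 (2.51 ± 0.13); median 1.07, camera adjusted p = 0.000161, adjusted p = 0.2505 with estimated correlation). Short-lived transcripts went up as a group (20 up and 4 down of 34, or 22 and 4 over the list alone; median 0.84, camera adjusted p = 0.000785, adjusted p = 0.2505 with estimated correlation), with ID2 (2.97 ± 0.07) and DUSP1 (3.48 ± 0.11) up but cyclin D1 gene CCND1 (-4.40 ± 0.11) and XIAP (-2.08 ± 0.06) down. Cholesterol synthesis genes rose (12 up and 2 down of 18, or 12 and 2 over the list alone, with HMGCS1 (1.44 ± 0.07), IDI1 (1.97 ± 0.11) and INSIG1 (1.86 ± 0.12)), as did neuronal and neuroendocrine genes (10 up and 1 down of 31, or 9 and 1 over the list alone, with the synaptotagmin SYT11 (2.49 ± 0.11) and neurofilament NEFH (3.84 ± 0.30) up but SYT4 (-3.00 ± 0.13) down), with camera adjusted p from 0.00127 to 0.0106, adjusted p from 0.124 to 0.296 with estimated correlation.

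Cell cycle genes fell with TSA: 26 of 30 genes of G2 and mitosis, with CDK1 (-1.89 ± 0.07), UBE2C (-2.22 ± 0.12) and AURKB (-1.95 ± 0.13) (median -0.98, camera adjusted p = 1.64e-09, adjusted p = 0.297 with estimated correlation). So did 24 of 30 S-phase genes, with the thymidylate synthase gene TYMS (-3.06 ± 0.08) and the helicase subunit MCM7 (-1.55 ± 0.09) (median -0.87, camera adjusted p = 7.06e-08, adjusted p = 0.305 with estimated correlation). In each list 1 member rose. Epithelial genes fell (2 up and 15 down of 24, or 2 and 15 over the list alone, with the transcription factor GRHL2 (-2.60 ± 0.09) and the splicing regulator ESRP1 (-1.84 ± 0.09); median -0.59, camera adjusted p = 0.000365, adjusted p = 0.2505 with estimated correlation). Androgen receptor targets fell (3 up and 13 down of 20, or 4 and 13 over the list alone; median -0.92, camera adjusted p = 0.000785, adjusted p = 0.2505 with estimated correlation), with the transporter ABCC4 (-2.77 ± 0.07) down but the elongation factor EAF2 (2.17 ± 0.08) up. The unfolded protein and ATF4 response list fell (5 up and 15 down of 26, or 6 and 15 over the list alone, with SLC7A11 (-3.21 ± 0.09), XBP1 (-2.34 ± 0.07) and TRIB3 (-2.78 ± 0.12); median -0.52, camera adjusted p = 0.00530, adjusted p = 0.2505 with estimated correlation). Of p53 targets 15 fell and 7 rose of 24, with GDF15 (-2.37 ± 0.07) and PHLDA3 (-2.44 ± 0.13) down (median -0.52, camera adjusted p = 0.0489, adjusted p = 0.338 with estimated correlation), and that call was lost without DMSO replicate 2 or any Roscovitine or wild-type add-back array (median -0.52, adjusted p from 0.05004 to 0.0765). EZH2-repressed genes did not pass (median 0.22, camera adjusted p = 0.0779, adjusted p = 0.2505 with estimated correlation). Of its members, 9 rose, 5 fell and 7 did not pass (10 up and 5 down over the list alone). Among those called were CDKN1C (3.76 ± 0.12), TIMP3 (3.47 ± 0.13) and RND3 (3.15 ± 0.12) up and BMPR1B (-2.91 ± 0.09) down. In total, limma called 4072 genes higher and 4240 lower of 19775 tested, 1262 and 1372 of them by more than 1 on the log2 scale, and 9396 had an unadjusted p under 0.05. Between 6981 and 8640 genes were called when 1 array was left out.

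Roscovitine against DMSO asked which genes respond to inhibition of CDKs. The largest falls were HEXIM1, an inhibitor of the kinase P-TEFb (-1.75 ± 0.07, signal from 1349 to 389), THBS1, thrombospondin (-1.71 ± 0.29), the transcription factor RFX6 (-1.55 ± 0.08), CHAC1, induced by ATF4 (-1.44 ± 0.15), RIN2 (-1.42 ± 0.12) and the receptor TNFRSF19 (-1.32 ± 0.07) (adjusted p from 2.32e-05 to 0.0185). The largest rises were the non-coding transcripts LOC90246 (1.39 ± 0.13) and LINC01503 (1.19 ± 0.17) and FOXD3-AS1 (1.05 ± 0.19, signal from 6.45 to 31.05), the kinesin KIF26A (1.15 ± 0.23, signal from 11.9 to 45.6), the RNA helicase DDX5 (0.99 ± 0.14) and the GTPase RAB26 (0.98 ± 0.13) (adjusted p from 0.00279 to 0.0349). LOC90246, HEXIM1, RFX6, RIN2 and TNFRSF19 were called in all 14 fits that left out 1 array. CHAC1 was lost without DMSO replicate 2, and LINC01503, KIF26A, FOXD3-AS1, DDX5, RAB26 and THBS1 each without either DMSO array and also without 1 or both Roscovitine arrays. Further probe sets differed less (0.29 for LOC90246 and -0.0055 for RIN2) or had the opposite sign (0.16 for HEXIM1 and 0.37 for THBS1).

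Of 30 genes of G2 and mitosis 0 rose, 18 fell and 12 did not pass (0 up and 28 down over the list alone). The calls included the centromere motor CENPE (-1.04 ± 0.09), the kinases TTK (-0.91 ± 0.09) and BUB1 (-0.77 ± 0.08) and DLGAP5 (-0.82 ± 0.08). Together the list had a median of -0.66 (camera adjusted p = 3.51e-28, adjusted p = 0.277 with estimated correlation). S-phase genes did not pass as a group (median -0.041, camera adjusted p = 0.982, adjusted p = 0.987 with estimated correlation), and 1 rose, cyclin E gene CCNE1 (0.59 ± 0.10). Of 26 genes of the unfolded protein and ATF4 response 0 rose, 8 fell and 18 did not pass (2 up and 15 down over the list alone). They included DDIT3 (-1.11 ± 0.08), STC2 (-0.89 ± 0.09) and CEBPB (-0.61 ± 0.09). For the whole list this gave a median of -0.23 (camera adjusted p = 2.92e-05, adjusted p = 0.277 with estimated correlation). Androgen receptor targets were lower (median -0.19, camera adjusted p = 0.00836, adjusted p = 0.736 with estimated correlation), with MAF (-0.95 ± 0.12) and EAF2 (-0.42 ± 0.08) called. Histones were higher (median 0.14, camera adjusted p = 0.0351, adjusted p = 0.736 with estimated correlation), with H2AC6 (0.62 ± 0.07) called and 7 of 16 up over the list alone. The first of these calls was lost without Roscovitine replicate 1 (median -0.17, adjusted p = 0.0572), the second without DMSO replicate 1, Roscovitine replicate 1 or either wild-type add-back array (median 0.10 to 0.14, adjusted p from 0.0603 to 0.141). EZH2-repressed genes did not pass (median -0.015, camera adjusted p = 0.982, adjusted p = 0.987 with estimated correlation), the smallest adjusted p being that of CDKN1C (-0.40 ± 0.12) at 0.125. In total, limma called 109 genes higher and 437 lower of 19775 tested, 4 and 20 of them by more than 1 on the log2 scale, and 3098 had an unadjusted p under 0.05. The count was 34 without DMSO replicate 1, 21 without DMSO replicate 2 and 239 without Roscovitine replicate 1. It was 83 without Roscovitine replicate 2, 327 without either si-Control array and 343 without either si-EZH2 array. It was 1157 with only the genes of higher mean signal, 312 with the mean of all probe sets of a gene and 6 with the arrays of the same experiment alone. It was 933 with an intensity trend and robust prior and 120 without both deviating arrays, and the split after quantile normalization was 246 higher and 472 lower.

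**Figure D5:**
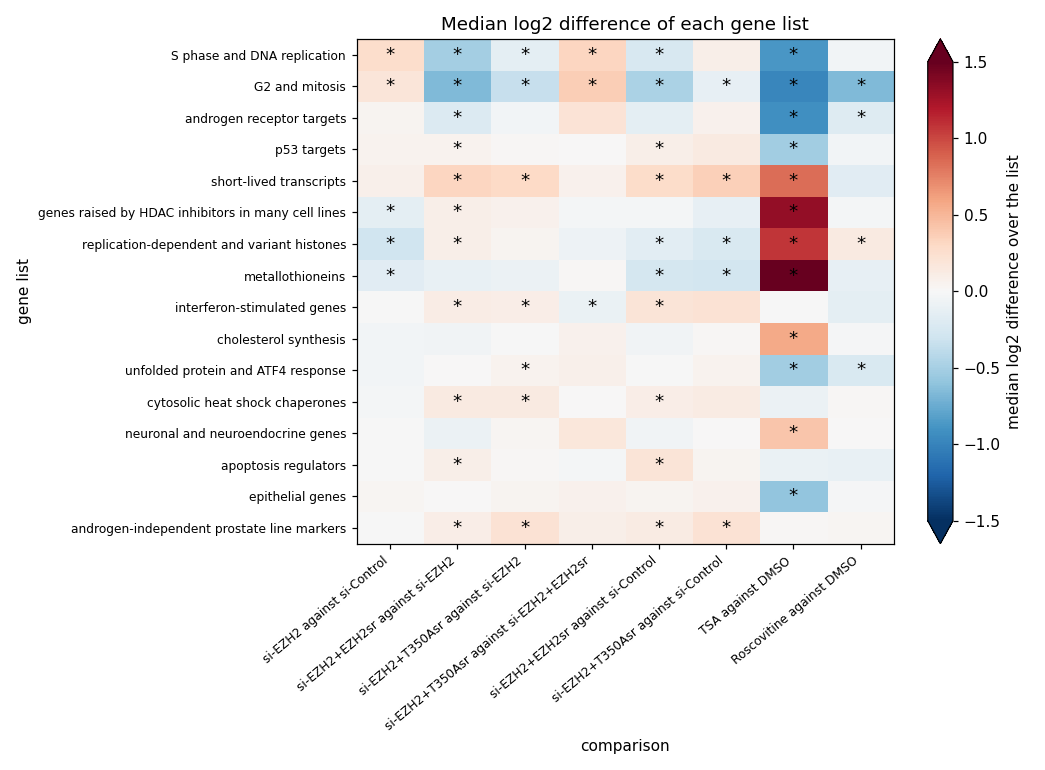
Median log2 difference of 16 gene lists (lines of the grid) in the 8 comparisons (columns) on a colour scale, with an asterisk where camera called the list at the preset correlation. G2 and mitosis is marked in 8 comparisons, from -0.98 with TSA to 0.37 for T350A against wild-type.

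The genes called in each treatment were then compared, to see whether genes raised by EZH2 knockdown also respond to HDAC or CDK inhibition. Of the 135 genes raised by si-EZH2, 46 also rose with TSA (27.8 for independent lists, odds ratio 2.00, 95% confidence interval 1.37 to 2.90, two-sided Fisher's exact p = 0.000246), and 58 fell with TSA (28.9, odds ratio 2.78, 95% confidence interval 1.94 to 3.97, two-sided Fisher's exact p = 1.88e-08). With Roscovitine 0 of them rose (0.744 for independent lists, with an odds ratio of at most 5.05 at 95% confidence) and 25 fell (2.98, odds ratio 10.6, 95% confidence interval 6.51 to 16.7, two-sided Fisher's exact p = 2.41e-16). TSA and Roscovitine shared 44 raised genes (22.4 for independent lists, odds ratio 2.63, 95% confidence interval 1.75 to 3.92, two-sided Fisher's exact p = 2.24e-06) and 254 lowered genes (93.7, odds ratio 5.35, 95% confidence interval 4.39 to 6.52, two-sided Fisher's exact p = 8.92e-64). These 2 comparisons share the DMSO arrays: across genes their log2 differences correlated with r = 0.134 against 0.502 in simulated unchanged groups, with a covariance of 0.0262 against 0.0176. Genes are not independent and all lists share the estimate of spread, some also arrays, so these tests overstate the evidence. The overlap of genes raised by si-EZH2 and TSA was 20 without DMSO replicate 1, 19 without DMSO replicate 2 and 26 without TSA replicate 1. It was 27 without TSA replicate 2, 8 without si-Control replicate 1 and 5 without si-Control replicate 2. It was 5 without si-EZH2 replicate 1, 4 without si-EZH2 replicate 2 and 70 without either wild-type add-back array. For TSA and Roscovitine the overlap was 4 without DMSO replicate 1, 2 without DMSO replicate 2 and 26 without TSA replicate 1. It was 24 without Roscovitine replicate 1, 4 without Roscovitine replicate 2 and 29 without either si-Control array, and for si-EZH2 and Roscovitine 3 without either wild-type add-back array and 1 without either T350A add-back array. Under other settings the overlap for si-EZH2 and TSA was 125 with only the genes of higher mean signal, 29 with each array at the same median and 21 with the mean of all probe sets of a gene. It was 2 with the arrays of the same experiment alone, 85 with an intensity trend and robust prior and 81 with a term shared by both deviating arrays. The one for TSA and Roscovitine was 122 with only the genes of higher mean signal, 107 after quantile normalization and 26 with the mean of all probe sets of a gene. It was 0 with the arrays of the same experiment alone, 90 with an intensity trend and robust prior and 5 without both deviating arrays. That for si-EZH2 and Roscovitine was 7 with only the genes of higher mean signal, 1 with pseudocount 64, 2 with an intensity trend and robust prior and 1 with a term shared by both deviating arrays.

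A second deposited table held 7022 of the 54613 probe sets with the same signals (all 98308 values equal within 0.005), although its heading describes ratios to the si-Control mean. Its set is not independent evidence, since the values themselves show how it was chosen. In 7022 of these probe sets the si-EZH2 mean was above si-Control, in 7022 above the wild-type add-back, in 6976 the T350A mean was above wild-type, in 7020 TSA was above DMSO, and in 7022 the DMSO mean was 0.6 to 1.4 times si-Control. All 5 conditions held for 6974 of them and for 1 of the other 47591 probe sets. Simulated arrays without any effect gave 5173 such probe sets on average (range 5029 to 5295 in 20 draws), and the same orderings turned round held for 3113. Of the set, limma over all probe sets called 10 higher in si-EZH2 than si-Control, 572 lower in wild-type than si-EZH2, 1 higher in T350A than wild-type, and 2482 higher with TSA, and 4 in both of the first 2 orderings. No probe set was called in all 4.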

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

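The tests on explanations in this part were all chosen after the results were seen. The first pattern is that genes raised by si-EZH2 stayed high after EZH2 was returned: 68 of 135 were still called above si-Control with wild-type and 71 with T350A (50.4% and 52.6%), against 0% to 0.198% of raised genes in 20 simulations with both add-back groups equal to si-Control and 58.3% to 68.9% with both equal to si-EZH2, although these raised 440 to 602 genes. A low level in the si-Control arrays is a candidate explanation: in DMSO, untransfected cells with 91.7% of the si-Control EZH2 signal, these genes had a median 0.917 of their si-EZH2 rise over si-Control, against 0.0779 to 0.118 in simulations where DMSO equals si-Control, and 29 of them were also called higher in si-EZH2 than in DMSO. Release from EZH2 as the cause in the whole set is argued against by the lower quartile of that share, 0.557, although drug and transfection cells also differ in time and handling. For the 30 genes with DMSO nearer to si-Control, a release from EZH2 that needs T350 cannot be told apart from no difference: the T350A share of the rise minus the wild-type share had a median of 0.152 with quartiles -0.0537 and 0.337. Of these genes 15 were called lower than si-EZH2 with wild-type and 2 with T350A, at unlike cut-offs, and limma called 0 higher in T350A than in wild-type.

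The second pattern is a rise of chemokines and other genes in both add-back groups: 114 genes besides EZH2 rose in both over si-EZH2, by a median of 1.57, and 24 of them are among 51 measured NF-kappaB and TNF targets, a list set up after these rises were seen, of which 31 rose with wild-type and 24 with T350A. Higher mean EZH2 mRNA is argued against as cause. With more of it, si-Control exceeded si-EZH2 by an upper quartile of 0.110 of the add-back rise. EZH2 per cell and protein were not measured. Leukocytes, fibroblasts and endothelium are argued against as source of the whole pattern. Their highest marker, CLDN5, had a mean add-back difference of 0.42, and PTPRC 0.00592. With androgen-independent lines, the upper quartile was 0.19 over 47 markers, or 0.20 over 49 with CXCL8 and IL6, left out as NF-kappaB targets. VIM had 0.093. Pooling cannot exclude such a line. Camera called its markers up in both (adjusted p = 0.0150 and 0.00139, with estimated correlation 0.243 and 0.310). CXCL8 was called in both and LAMB3 with wild-type (2.54). Delivery of plasmid cannot be told apart from an effect that both EZH2 proteins share, because no group received plasmid without EZH2. By selection these genes rose in both (T350A minus wild-type median -0.0576, quartiles -0.35 and 0.17, 2 of 114 called different).

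The third pattern is the difference between T350A and wild-type, where 40 genes changed differently from si-EZH2 by a direct test, 14 of them on the list of hypoxia-inducible genes. The 2 arrays that deviate together are argued against as the whole cause, since wild-type minus si-EZH2, which holds neither, had a lower quartile of 0.27 and a median of 0.69 over the list, set up after these values were seen (0.24 and 0.49 over the 36 members not called between the add-back groups). A fall caused by T350A EZH2 is argued against, since T350A minus si-EZH2 over the list had a lower quartile of 0.0163 and a median of 0.078, so that the wild-type add-back stands apart. A difference between cultures, such as lower oxygen or denser cells in the wild-type group, cannot be told apart from an effect of wild-type EZH2: the list was above si-EZH2 in both wild-type arrays, by a median of 0.86 and 0.56, and both explanations predict this.

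Of the 13522 probe sets without a single gene symbol, limma over all probe sets called 10 in si-EZH2 against si-Control, 462 in wild-type and 22 in T350A against si-EZH2, 2 in T350A against wild-type, 248 in wild-type and 66 in T350A against si-Control, 2493 with TSA and 96 with Roscovitine.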

How the results depend on the processing

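Only the alternatives for both deviating arrays were chosen after the data were seen. Where 1 array of a group was left out, the lone array is assumed to vary like the other groups. The count for TSA stayed within 1.5 times its value under every alternative, and the number of list calls, 57, under every alternative except the estimated correlation, which gave 0 (fry called 66, and 25 had an unadjusted p under 0.05). Of 1482 values of called lists under the alternatives 1323 kept their call and 159 lost it, and of 22887 values of named genes 20691 kept their result, 1527 lost a call, 519 gained one, 149 changed sign without a call either way and 1 reversed. The low level of many genes limits what can be seen, as background and signal are not separated under 50. The lower counts with the arrays of 1 experiment alone follow in part from fewer residual degrees of freedom, and the higher ones with only brighter genes come with fewer genes tested (9887). Otherwise the cause was not tested. The replicate block had no support in the labels.

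With an estimated correlation the raised-gene shift of 0.0952 had p = 0.101. With only the genes of higher mean signal the counts were 422 for si-EZH2 against si-Control, 402 for T350A against si-EZH2, 164 for T350A against wild-type, 787 for T350A against si-Control, 1157 for Roscovitine, 125 for genes raised by si-EZH2 and TSA, 7 for genes raised by si-EZH2 and Roscovitine and 122 for genes raised by TSA and Roscovitine. After quantile normalization the counts were 77 for T350A against wild-type and 107 for genes raised by TSA and Roscovitine. The shift was 0.0264 for raised (camera at the preset correlation, p = 0.130) and -0.0310 for lowered genes. With each array at the same median the counts were 78 for T350A against wild-type and 29 for genes raised by si-EZH2 and TSA. The shift was 0.00790 for raised (camera at the preset correlation, p = 0.261) and -0.0724 for lowered genes. With pseudocount 64 the counts were 247 for si-EZH2 against si-Control, 265 for T350A against si-EZH2, 74 for T350A against wild-type and 1 for genes raised by si-EZH2 and Roscovitine. With the mean of all probe sets of a gene the counts were 83 for si-EZH2 against si-Control, 14 for T350A against wild-type, 312 for Roscovitine, 21 for genes raised by si-EZH2 and TSA and 26 for genes raised by TSA and Roscovitine, and CDKN2A in wild-type against si-EZH2 was -0.0402 and the shift of the lowered genes was -0.0630. With the arrays of the same experiment alone the counts were 5 for si-EZH2 against si-Control, 244 for wild-type against si-EZH2, 4 for T350A against si-EZH2, 0 for T350A against wild-type, 238 for wild-type against si-Control, 20 for T350A against si-Control, 6 for Roscovitine, 2 for genes raised by si-EZH2 and TSA and 0 for genes raised by TSA and Roscovitine, and the shift of the raised genes was 0.0466 (camera at the preset correlation, p = 0.634). With a replicate block the counts were 21 for si-EZH2 against si-Control, 103 for T350A against si-EZH2, 0 for T350A against wild-type, 972 for wild-type against si-Control, 236 for T350A against si-Control, 202 for Roscovitine, 5 for genes raised by si-EZH2 and TSA and 13 for genes raised by TSA and Roscovitine, and the shift of the raised genes was 0.0840 (camera at the preset correlation, p = 0.0739). With an intensity trend and robust prior the counts were 314 for si-EZH2 against si-Control, 369 for T350A against si-EZH2, 112 for T350A against wild-type, 714 for T350A against si-Control, 933 for Roscovitine, 85 for genes raised by si-EZH2 and TSA, 2 for genes raised by si-EZH2 and Roscovitine and 90 for genes raised by TSA and Roscovitine, and the shift of the lowered genes was -0.00370. Without both deviating arrays the counts were 320 for T350A against si-EZH2, 119 for T350A against wild-type, 120 for Roscovitine and 5 for genes raised by TSA and Roscovitine. With a term shared by both deviating arrays the counts were 275 for si-EZH2 against si-Control, 81 for genes raised by si-EZH2 and TSA and 1 for genes raised by si-EZH2 and Roscovitine. Where limma called 0 genes for T350A against wild-type, 2425 (1 experiment) and 2948 (replicate block) had an unadjusted p under 0.05. The 4 negative shifts of the lowered genes had camera p under 0.05 at the preset correlation.

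Over the 14 fits that left out 1 array each, the counts ranged from 16 to 280 for si-EZH2 against si-Control, 458 to 2800 for wild-type against si-EZH2, 31 to 338 for T350A against si-EZH2, 0 to 1008 for T350A against wild-type, 381 to 2328 for wild-type against si-Control, 74 to 619 for T350A against si-Control, 6981 to 8640 for TSA, 21 to 745 for Roscovitine, 4 to 70 for genes raised by si-EZH2 and TSA, 0 to 3 for genes raised by si-EZH2 and Roscovitine and 2 to 59 for genes raised by TSA and Roscovitine. The list calls ranged from 51 to 58, and the shift of the raised genes from 0.0279 to 0.167.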

Other observations

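Several fixed lists were called by camera in none of the 8 comparisons, although TSA changed some of their members. Of 49 developmental transcription factors bound by PRC2 in embryonic stem cells, TSA raised 16, such as the neuronal factor ISL1 (2.60 ± 0.16), and lowered 4, such as FOXA1, a pioneer factor of the androgen receptor (-3.20 ± 0.10), ZIC2 (-2.05 ± 0.13) and TBX3 (-1.32 ± 0.08) (median 0.20, camera adjusted p = 0.0747, adjusted p = 0.296 with estimated correlation). Of 29 cyclins, CDKs and CDK inhibitors 13 rose and 11 fell with TSA (median -0.057, camera adjusted p = 0.948, adjusted p = 0.974 with estimated correlation), with CDKN1C (3.76 ± 0.12) up and CDK4 (-1.41 ± 0.08) down. In the wild-type add-back against si-EZH2 the CDK inhibitor CDKN2B (2.02 ± 0.37) rose and CCNA2 (-0.86 ± 0.11) and CCNB1 (-0.69 ± 0.12) fell (median -0.056, camera adjusted p = 0.880, adjusted p = 0.925 with estimated correlation). PRC2 and PRC1 subunits moved both ways with TSA: JARID2 (1.09 ± 0.08) and MTF2 (0.74 ± 0.10) of PRC2 and RYBP (0.86 ± 0.07) and RING1 (0.78 ± 0.09) of PRC1 rose, while RBBP4 (-0.76 ± 0.09) and AEBP2 (-0.51 ± 0.06) of PRC2 and PCGF6 (-1.01 ± 0.11) and PCGF2 (-0.80 ± 0.09) of PRC1 fell, in all 3 up and 4 down of 11 PRC2 subunits (median 0.14, mean 0.041, camera direction down) and 5 up and 6 down of 14 PRC1 subunits (median -0.07), with camera adjusted p = 0.948, adjusted p = 0.974 with estimated correlation. Of 28 HOX genes TSA lowered 5, with HOXC6 (-2.47 ± 0.14) and HOXB13 (-0.99 ± 0.14), and raised 1, HOXB8 (0.55 ± 0.09) (median -0.0002, camera adjusted p = 0.881, adjusted p = 0.974 with estimated correlation).

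Of 29 mesenchymal genes 6 rose and 3 fell with TSA, with VIM (1.29 ± 0.08) up and CALD1 (-1.88 ± 0.08) down (median 0.095, camera adjusted p = 0.631, adjusted p = 0.625 with estimated correlation), and in the wild-type add-back the matrix gene FBN1 (3.00 ± 0.35) rose over si-EZH2 (median -0.057, camera adjusted p = 0.159, adjusted p = 0.283 with estimated correlation), where the median was below 0 and the mean and test above. Ribosomal protein genes had 1 of 27 called with TSA, RPLP2 (0.38 ± 0.08) (median -0.0086, camera adjusted p = 0.948, adjusted p = 0.974 with estimated correlation). Leukocyte markers had 1 of 16, PTPRC (-0.62 ± 0.13) (median -0.025, camera adjusted p = 0.881, adjusted p = 0.974 with estimated correlation), and fibroblast and endothelial markers 1 up and 2 down of 18, with COL1A1 (1.49 ± 0.15) up and VWF (-0.70 ± 0.11) and COL3A1 (-0.78 ± 0.15) down (median 0.059, camera adjusted p = 0.948, adjusted p = 0.974 with estimated correlation). Over the 8 comparisons the smallest camera adjusted p of any of these lists was 0.0747.

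The SD over 9887 genes of the log2 difference between both arrays of a group was 0.237 for Roscovitine, 0.286 for the T350A add-back, 0.195 for the wild-type add-back and 0.0977 to 0.126 for the other 4 groups, and 49, 106 and 2 genes in the first 3 groups were more than 1 apart. The arrays held 5 isolated signals over 100 times the median and over 50 times the highest signal of the probe set on the other arrays: CCDC68 in TSA replicate 2 (14194 against at most 18.3), OGN (1812) and CGAS (1339) in Roscovitine replicate 2, SYNJ2 in si-EZH2 replicate 2 (109943), and a probe set without a symbol in si-Control replicate 1 (1570775).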
